A study of Homo sapiens with 15 samples.

How the data were processed

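Ribosome profiling libraries of human HEK293 cells were measured in 15 samples, 3 in each of 5 groups. Per the labels, the Flag/HA lines were induced with doxycycline at 1 µg/mL for 24 h, lysed in a hypotonic buffer and footprinted with RNase I. The parental line and the line labelled ZC3H7A knockout with a hairpin against ZC3H7B were selected with puromycin at 5 µg/mL and lysed as frozen pellets in a polysome buffer with cycloheximide at 100 µg/mL. These 2 sets differ in lysis, kit and laboratory, so they were compared only by their fold changes. Exceptions are 1 test for mixed reads that used levels of marker genes, and the levels of NALCN, HDX and HIST1H2AL.

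The deposited table gives a normalized signal for 55773 gene names in the 15 samples, normalized counts per the file name, made by the authors before deposit. The submitters' processing notes name cutadapt, Bowtie, STAR, HTSeq and DESeq2 and the builds hg38 and hg19, without versions or roles. Which build the reads were aligned to, the footprint lengths kept and how reads with several positions were treated are not given in the sources used here. Every low value of a library was a whole multiple of 1 step. Dividing by that step gave whole reads for 100% of values, within 0.001 reads, so the reads and depths could be recovered. Values were therefore taken as reads per gene divided by a size factor for each library. Counting intervals and floors use the recovered reads, at 95% confidence and with 3 counts as the floor. They cover counting error only, since no molecular identifiers are named.

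A total of 10735 gene names had no read in any library. Names were matched to current symbols (35385) and to GENCODE release 29 (35494). A coding sequence of at least 30 codons was found for 18992, and the longest was used. AT3 is the percentage of its codons, without the start and stop codons, that end in A or T. The table holds 28 names that a spreadsheet turned into dates, with 0.173% to 0.285% of reads, and 4 duplicated names. These could not be assigned and take part only as unnamed genes.

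Values were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend) on log2(value + 1), for genes at 10 or more in at least 3 samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 9 Flag/HA libraries shared 1 fit with 3 contrasts, and the other 6 libraries were fitted apart. On the recovered reads, edgeR 4.0.16 (quasi-likelihood) called 9059, 8494, 5856 and 4132 genes and DESeq2 1.42.0 called 8528, 7934, 5360 and 4193, for ZC3H7A, ZC3H7B, ZC3H7A against ZC3H7B and the libraries labelled ZC3H7A/B-DD. The 24 gene lists of 1176 genes were tested with limma's camera at a correlation of 0.01 and with an estimated one. They cover cytosolic ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, mitochondrially encoded proteins, the nuclear-encoded respiratory chain, KRAB zinc fingers, histones, mitosis, DNA replication and repair and the integrated stress response. Further lists are the unfolded protein response, heat shock, interferon-stimulated genes, p53 targets, cholesterol synthesis, glycolysis and hypoxia, mRNA decay, microRNA machinery and the proteasome. Matrix and adhesion, neuronal, HOX, immediate early genes and markers of fibroblasts and blood cells complete them. All list calls at the preset correlation were lost with the estimated one.

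The genes named are the targets and, for each comparison with a control, the 10 highest and 10 lowest log2 changes (5 and 5 between the overexpressing lines). They had to pass the test, have all 3 libraries above or below the other 3, and reach a mean of 20 in either group. From each list up to 2 called members per direction with the smallest p were taken. Results of a few genes that met this rule are not reported here. Lists, this rule, the main tests and the alternatives were chosen before the data were examined, except those stated elsewhere as chosen later. Slopes on AT3 per library were compared by exact permutation, and directions of calls by Fisher's exact test. Shared controls were simulated 100 times.

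The limma step was tested on simulated data with 200 changed genes drawn from the real means and depths. For ZC3H7A (15341 genes in the step) it recovered 82.1%, 95.5% and 100% of 1.5-, 2- and 4-fold changes, with 4.6% of calls false. For ZC3H7B (15339 genes) these were 77.6%, 92.5% and 98.5%, with 3.2% false, and for ZC3H7A against ZC3H7B (15325 genes) 74.6%, 91.0% and 100%, with 4.3% false. For the libraries labelled ZC3H7A/B-DD (16774 genes) only 31.3% of 1.5-fold changes were recovered, with 82.1% and 97.0% of 2- and 4-fold changes and 11.4% of calls false. Replicates differed by 1.65 to 6.06 times counting noise (chi-square per degree of freedom) in the Flag/HA groups and by 8.73 to 87.9 in the other 2, where both highest values involve parental replicate 3. Alternatives were other pseudocounts, filters and scalings, precision weights, a replicate block, the count tests, other spreads, GC content in place of AT3, and each library left out in turn. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Translational efficiency was left out because the RNA libraries were not used here.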

Results

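Ribosome footprints were sequenced from human HEK293 cells, an established embryonic kidney line, in 15 libraries that form 5 groups of 3. In 3 of these groups a doxycycline-inducible HEK293 line carried a Flag/HA tag alone, tagged ZC3H7A or tagged ZC3H7B, and the labels describe their samples as 3 independent replicates. ZC3H7A and ZC3H7B are related CCCH-type zinc finger proteins. The other 2 groups were a parental line with a control short hairpin RNA and a line labelled as a ZC3H7A knockout with a hairpin against ZC3H7B. Nothing in the labels says whether their replicates are independent cultures, so p-values there measure only the spread between these samples, which may be technical. Libraries held 28261810 to 29515572 assigned reads in the Flag/HA control, 24703005 to 25922138 with ZC3H7A and 22661812 to 25939425 with ZC3H7B. Parental libraries held 32955833 to 39064072, and the libraries labelled ZC3H7A/B-DD 20777204 to 42680589. Between 97.7% and 98.8% of reads fell in protein-coding genes. Mitochondrial ribosomal RNA took 0.0042% to 0.0095% of reads in the Flag/HA libraries and 0.401% to 0.994% in the other 6, which were lysed and prepared by another protocol. Footprints alone do not separate a change in mRNA level from a change in translation, and the matched RNA sequencing that the labels mention was not used here. All values are reads per gene divided by a size factor, called normalized counts here, with the SD over 3 libraries per group. Log2 changes are on the log2(value + 1) scale, which understates the change of low genes.

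The targeted genes were examined first, in every library. ZC3H7A (chromosome 16, 11750586 to 11797267, GRCh38) stood at 6548 ± 52.6 normalized counts in the Flag/HA control and rose to 38044 ± 562 in the ZC3H7A-overexpressing cells, a log2 change of 2.54 (limma adjusted p = 3.43e-23). ZC3H7B (chromosome 22, 41301522 to 41360147) stood at 2152 ± 71.8 in the control and rose to 27885 ± 927 in the ZC3H7B-overexpressing cells (log2 change 3.695, limma adjusted p = 6.71e-25). Each gene also moved in the other line. ZC3H7A fell to 4762 ± 80.6 with ZC3H7B overexpression (log2 change -0.46, limma adjusted p = 1.25e-09), and ZC3H7B rose to 2820 ± 162 with ZC3H7A overexpression (log2 change 0.39, limma adjusted p = 2.44e-07). Neither gene was lower in the libraries labelled ZC3H7A/B-DD. ZC3H7A footprints stood at 7116, 1890.3 and 5066 in replicates 1 to 3, against 1885, 1820 and 2311 in the parental libraries. Their means were 4691 ± 2633 and 2005 ± 267 (log2 change 1.03, limma adjusted p = 0.085). The change was 0.63 without replicate 1 of that group and 1.59 without replicate 2, and of the single libraries left out only the latter gave a call (limma adjusted p = 0.00124). ZC3H7A was also called higher with precision weights in limma (1.30, adjusted p = 0.000679), with 1 spread for all 15 samples (limma adjusted p = 0.00831), without the filter (limma adjusted p = 0.01745) and by edgeR in place of limma (adjusted p = 0.0489), but not by DESeq2 (adjusted p = 0.0805). ZC3H7B stood at 3948, 2399 and 2969 against 2479, 2321 and 2609, with means of 3106 ± 784 and 2470 ± 144 (log2 change 0.30, limma adjusted p = 0.198). Without replicate 2 its change was 0.47 (limma adjusted p = 0.0463), and with precision weights 0.36 (limma adjusted p = 0.00831). A knockout allele can leave a footprinted transcript, so footprint levels do not settle whether ZC3H7A protein was lost. This does not account for ZC3H7B, which was targeted by a hairpin and was not lower. The labels' direction is therefore carried with each result for these libraries below.

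**Figure D1:**
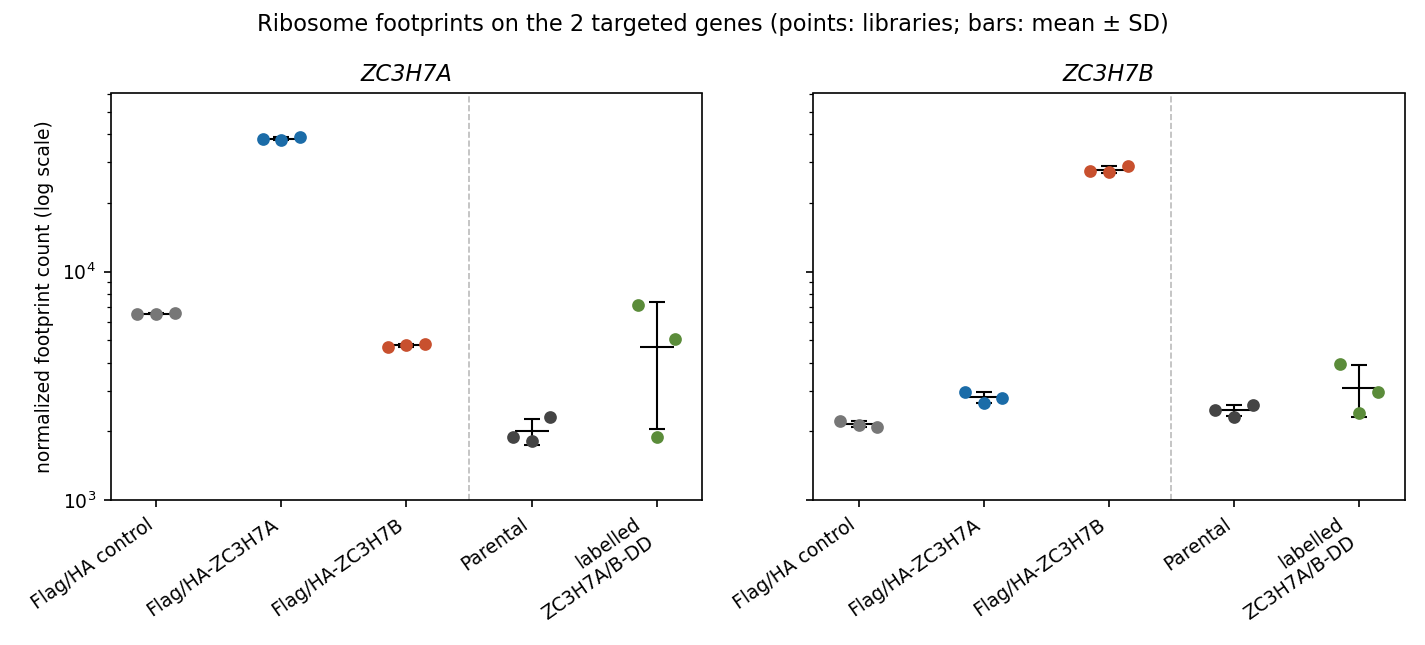
Normalized footprint counts (log axis) of ZC3H7A and ZC3H7B in each of the 15 libraries, with points for libraries and bars for group means. ZC3H7A lies above every parental library in replicates 1 and 3 of the libraries labelled ZC3H7A/B-DD, at 7116 and 5066.

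Overexpression of ZC3H7A was set against the Flag/HA control to find which footprint levels change when this protein is added. Each construct was measured in its own line. Differences between lines are therefore not told apart from a response to the protein, here and with ZC3H7B. The strongest rises were of genes nearly silent in control cells. NALCN, a sodium leak channel, stood at 504 ± 45.9 against 2.01 ± 2.48 (log2 change 7.74). The DNA sensor IFI16 reached 1670.1 ± 103 against 8.65 ± 4.46 (7.56). MFAP2, a microfibril component, fell from 596 ± 26.3 in the control to 1 read over 3 libraries, and the P-cadherin gene CDH3 from 648 ± 12.5 to 18.9 ± 3.61 (log2 change -5.05). In all, 8964 of 15599 genes tested passed the limma test, 4559 higher and 4405 lower, and the median size of a called change was a log2 change of 0.455. At least 2-fold changes were called for 1352 genes, 850 higher and 502 lower. In 9966 genes (63.9%) the 3 overexpressing libraries lay all above or all below the 3 controls, against 10% by chance. By the naming rule, each gene named here for the size of its change is among them.

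Further genes near silent in the control line and high in the ZC3H7A line were HDX, a homeobox gene, at 277 ± 50.9 normalized counts, and RPH3A, a synaptic vesicle protein, at 252 ± 20.2. Only 2 control reads each were counted for HDX and RPH3A, and the 95% counting intervals of their ratios were 92.7 to 2782 and 84.3 to 2531. THNSL2 and ZNF22 had 1 control read each, with intervals of 36.2 to 8108 and 25.9 to 5834. HTRA3, a secreted serine protease, was at 0 in the control and at least 51.0-fold higher, taking a floor of 3 counts over the group. HIST1H2AL reached 472 ± 51.2 against 3.32 ± 0.804 and HIST1H2BI 212 ± 22.8 against 2.88 ± 1.41. HIST1H2AL was also high in the parental libraries, prepared by another protocol. A Flag/HA control line that is itself low in HIST1H2AL therefore stays open. Among genes that went down, the GABA transporter SLC6A11 was at 0 and at least 120.6-fold lower, TMEM171 at 0 and at least 57.8-fold lower, and LINC00958 at 0 and at least 18.7-fold lower. IGFBP7, which binds insulin-like growth factors, fell from 647 ± 60.3 to 29.6 ± 1.61 (log2 change -4.40). The antiviral synthetase OAS3 fell from 83.1 ± 7.58 to 1.78 ± 0.717 (-4.94). MFAP2, PABPC4L and NCAM2 had 1 read each in overexpressing cells and RAMP2 had 3. Their control levels were 238 to 52510, 21.3 to 4800, 11.2 to 2581 and 13.7 to 200.4 times higher by the 95% counting interval.

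Among the 24 gene lists, replication-dependent histones and KRAB zinc finger genes had the smallest p in limma's camera with ZC3H7A, both rising. Of 42 histone genes tested, 32 rose and 1 fell, and 33 rose and 1 fell when adjusted over the list alone (limma's camera adjusted p = 2.51e-11, and adjusted p = 0.348 with an estimated correlation). HIST1H2AE stood at 6897 ± 544 against 642 ± 20.2 (log2 change 3.42) and HIST1H2BG at 2701 ± 107 against 230.2 ± 30.6 (3.55), while HIST1H4I fell (-1.14). KRAB genes encode DNA-binding repressors, and 159 of 245 rose while 18 fell (161 and 19 adjusted over the list alone, camera adjusted p = 2.68e-12, adjusted p = 0.0808 with an estimated correlation). ZNF677 rose to 440 ± 27.1 from 18.6 ± 2.44 and ZNF320 to 590 ± 15.5 from 49.0 ± 14.2, whereas ZNF610 fell from 67.1 ± 12.9 to 3.64 ± 2.17 and ZNF483 fell by 0.65 on the log2 scale. Histone and zinc finger genes have near-identical copies that can share reads, so values of single members are uncertain. The HOX genes, which set positional identity, also rose, 24 of 36 with 3 lower (24 and 4 adjusted over the list alone, camera adjusted p = 8.41e-05, adjusted p = 0.47 with an estimated correlation). HOXA13 went from 992 ± 72.9 to 2502 ± 140 (log2 change 1.33) and HOXA9 from 940 ± 92.7 to 2022 ± 140 (1.11), while HOXA5 and HOXA7 fell by 0.27 and 0.83 on the log2 scale.

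Stress and secretory lists moved in different directions with ZC3H7A. Of 36 integrated stress response genes, which act in amino acid supply and stress adaptation, 24 rose and 6 fell (25 and 6 adjusted over the list alone, camera adjusted p = 0.000196, adjusted p = 0.348 with an estimated correlation). The transcription factor CEBPG rose to 7395 ± 355 from 3338 ± 125 (log2 change 1.15) and the amino acid transporter SLC7A5 rose by 0.86, while ATF3 and SESN2 fell by 0.72 and 0.48. Genes of the unfolded protein response went down, 21 of 31 against 2 that rose, with the same counts adjusted over the list alone (camera adjusted p = 1.02e-05, adjusted p = 0.348 with an estimated correlation). The secreted ER factor MANF fell from 5115 ± 60.6 to 3119 ± 194 (log2 change -0.72) and DNAJC3 from 6759 ± 141 to 4361 ± 233 (-0.63). Of 35 interferon-stimulated genes, 25 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 6.39e-07, adjusted p = 0.315 with an estimated correlation). SAMD9 fell from 1133 ± 15.7 to 211 ± 12.0 (log2 change -2.42), whereas IRF7 and IFI16 rose. Extracellular matrix and adhesion genes fell in 33 of 46 cases and rose in 4, with the same counts adjusted over the list alone (camera adjusted p = 4.81e-07, adjusted p = 0.315 with an estimated correlation). The laminin gene LAMA4 fell from 14434 ± 389 to 5935 ± 173 (log2 change -1.28) and the proteoglycan AGRN by 1.43 on the log2 scale, while the matrix protein SPARC rose from 52.5 ± 7.96 to 404 ± 18.7 (2.93). Among 29 p53 targets, 18 fell and 3 rose (18 and 4 adjusted over the list alone, camera adjusted p = 0.000119, adjusted p = 0.0808 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, fell from 1536 ± 49.7 to 478 ± 28.5 (log2 change -1.68) and SESN1 fell by 1.09.

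Proliferation lists fell with ZC3H7A. DNA replication and repair genes fell in 49 of 76 cases and rose in 10, with the same counts adjusted over the list alone (camera adjusted p = 1.02e-05, adjusted p = 0.545 with an estimated correlation). RPA2, a single-stranded DNA binding protein, went from 6373 ± 59.6 to 3340 ± 139 (log2 change -0.93) and the primase PRIM1 fell by 0.86, while MCM10 and GINS1 rose (0.76 and 0.61). Mitosis genes fell in 29 of 60 cases and rose in 13, likewise adjusted over the list alone, but 25 fell and 23 rose with quantile scaling (camera adjusted p = 0.0377, adjusted p = 0.831 with an estimated correlation). HMMR fell from 8104 ± 156 to 3484 ± 291 (log2 change -1.22) and SMC4 by 0.87, and AURKA and KIF23 rose (0.53 and 0.43). That call was lost without control replicate 1 or ZC3H7A replicate 1 or 3 (adjusted p of limma's camera = 0.0718, 0.0534 and 0.0824). Of 77 cytosolic ribosomal proteins, 34 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.0109, adjusted p = 0.81 with an estimated correlation, 0.055 without ZC3H7A replicate 2). RPL8 rose from 18415 ± 630 to 32500 ± 2472 (log2 change 0.82) and RPL11 fell from 35481 ± 184 to 24747 ± 1262 (-0.52). Mitochondrially encoded proteins rose in 8 of 13 cases with 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.0393, adjusted p = 0.81 with an estimated correlation). MT-ATP6 rose by a log2 change of 0.37. This list lost its call without control replicate 1 (0.177) or ZC3H7A replicate 1 (0.0534) or 3 (0.0885), and with TMM scaling (0.0516). The nuclear-encoded respiratory chain fell in 32 of 74 cases and rose in 12, also adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.81 with an estimated correlation, 0.0727 without ZC3H7A replicate 3). NDUFS6 fell from 8945 ± 100.9 to 4692 ± 146 (log2 change -0.93) and CYC1 rose by 0.65. In the microRNA machinery 8 of 14 genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.348 with an estimated correlation). AGO2 rose from 1865 ± 52.4 to 3164 ± 39.99 (log2 change 0.76), DICER1 rose by 0.57 and PRKRA fell by 0.35.

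With ZC3H7B overexpressed, the question was the same for the other protein. TENM1, a teneurin adhesion receptor, showed the strongest fall, from 1459 ± 87.6 normalized counts to 12.1 ± 4.13 (log2 change -6.85). PVRL3, the adhesion protein nectin 3, fell from 783 ± 20.4 to 22.7 ± 3.81 (-5.06) and the zinc finger gene ZNF43 from 209 ± 28.9 to 4.37 ± 1.60 (-5.33). NALCN rose to 71.7 ± 5.35 (log2 change 4.95), and the mucin MUC16, which encodes the antigen CA125, rose from 468 ± 23.7 to 5225 ± 755 (3.47). In the parental libraries, prepared by another protocol, NALCN stood at 80.9, 82.5 and 54.9. A Flag/HA control line that is itself low in NALCN therefore stays open. The limma test called 8475 of 15599 genes, 4509 higher and 3966 lower, with 1193 at least 2-fold changed (778 higher, 415 lower). In 9538 genes (61.1%) the 2 groups' libraries did not overlap, against 10% by chance. Other genes with the largest rises were CGREF1 (183 ± 25.6 against 9.91 ± 2.51), ZNF677 (324 ± 8.23 against 18.6 ± 2.44), the pseudogene EIF3FP1 (log2 change 4.05), MAGEC2 (3.59), PAPPA2 (3.55), the autophagy kinase ULK2 (3.49) and the matrilin MATN3 (3.41). The synaptic protein SLITRK3 was at 0, at least 26.8-fold lower. With 1 to 3 reads left, SLC6A11, TMEM171 and ZNF595 were 38.3 to 549, 22.1 to 673 and 18.3 to 560 times lower by the 95% counting interval. DLGAP1 and ZNF502 fell too, with log2 changes of -5.22 and -4.64.

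Histones, KRAB genes, the stress lists, p53 targets and matrix genes took the same direction with ZC3H7B as with ZC3H7A. Of 42 histone genes 36 rose and the other 6 did not pass, also adjusted over the list alone (camera adjusted p = 1.65e-12, adjusted p = 0.214 with an estimated correlation). HIST1H1D rose from 4131 ± 171 to 13322 ± 1413 (log2 change 1.68). Of 245 KRAB genes 157 rose and 24 fell (159 and 25 adjusted over the list alone, camera adjusted p = 3.48e-09, adjusted p = 0.157 with an estimated correlation), among them ZNF320 (3.39) and ZNF483 (-0.89). In the integrated stress response 22 of 36 genes rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.00273, adjusted p = 0.421 with an estimated correlation). ATF4, its central transcription factor, rose from 2969 ± 97.7 to 5466 ± 526 (log2 change 0.88) and CEBPG by 1.13, whereas the secreted factor GDF15 fell from 97.2 ± 7.67 to 19.0 ± 4.65 (-2.32). In the unfolded protein response 25 of 31 genes fell and 2 rose (26 and 2 adjusted over the list alone, camera adjusted p = 7.43e-10, adjusted p = 0.199 with an estimated correlation). ERO1L, an ER oxidase, fell from 8995 ± 99.5 to 3442 ± 133 (log2 change -1.39) and MANF by 1.03. Matrix and adhesion genes fell in 35 of 46 cases and rose in 3, also adjusted over the list alone (camera adjusted p = 2.04e-11, adjusted p = 0.157 with an estimated correlation). The integrins ITGAV (from 8917 ± 156 to 2562 ± 35.3, log2 change -1.80) and ITGA1 (-1.32) fell and the fibrillin FBN1 rose (0.97). Interferon-stimulated genes fell in 24 of 35 cases and rose in 2 (26 and 2 adjusted over the list alone, camera adjusted p = 2.05e-06, adjusted p = 0.214 with an estimated correlation), with SAMD9 at a log2 change of -1.18 and IRF7 at 1.86. Of 29 p53 targets 18 fell and 7 rose, also adjusted over the list alone (camera adjusted p = 0.00332, adjusted p = 0.157 with an estimated correlation). CDKN1A fell to 619 ± 3.43 (log2 change -1.31) and RRM2B by 0.97, and AEN and BBC3 rose (0.60 and 0.73).

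Cholesterol synthesis and mitochondrial lists also passed with ZC3H7B. Of 24 cholesterol genes 16 fell and 3 rose (17 and 3 adjusted over the list alone, camera adjusted p = 2.55e-05, adjusted p = 0.199 with an estimated correlation). The demethylase MSMO1 fell from 4808 ± 46.7 to 2301 ± 31.0 (log2 change -1.06) and SC5D by 1.11. Mitochondrially encoded proteins rose in 12 of 13 cases and the other 1 did not pass, also adjusted over the list alone (camera adjusted p = 8.45e-05, adjusted p = 0.445 with an estimated correlation). MT-ND1 rose from 11985 ± 1209 to 19053 ± 2532 (log2 change 0.67). Nuclear-encoded respiratory genes fell in 30 of 74 cases and rose in 14, also adjusted over the list alone, but 18 fell and 19 rose with quantile scaling (camera adjusted p = 0.0418, adjusted p = 0.828 with an estimated correlation), with NDUFB5 at -0.74 and UQCR11 at 0.58. This call was lost without control replicate 1 (0.1) or ZC3H7B replicate 3 (0.147). Neuronal genes, some of which HEK293 cells express, rose in 11 of 20 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 0.0432, adjusted p = 0.341 with an estimated correlation). INA, a neurofilament subunit, rose from 844 ± 4.99 to 2490.2 ± 145 (log2 change 1.56) and the vesicle protein SYP by 1.35, while MAP2 and SYT1 fell (-1.96 and -3.55). Their call was lost without control replicate 2 (0.0501) or ZC3H7B replicate 1 (0.0634) or 2 (0.0608). HOX genes rose in 15 of 36 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.0353, adjusted p = 0.659 with an estimated correlation, 0.101 without ZC3H7B replicate 3). HOXA13 rose by 1.16 and HOXA9 by 1.04, and HOXC11 fell by 0.38.

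**Figure D2:**
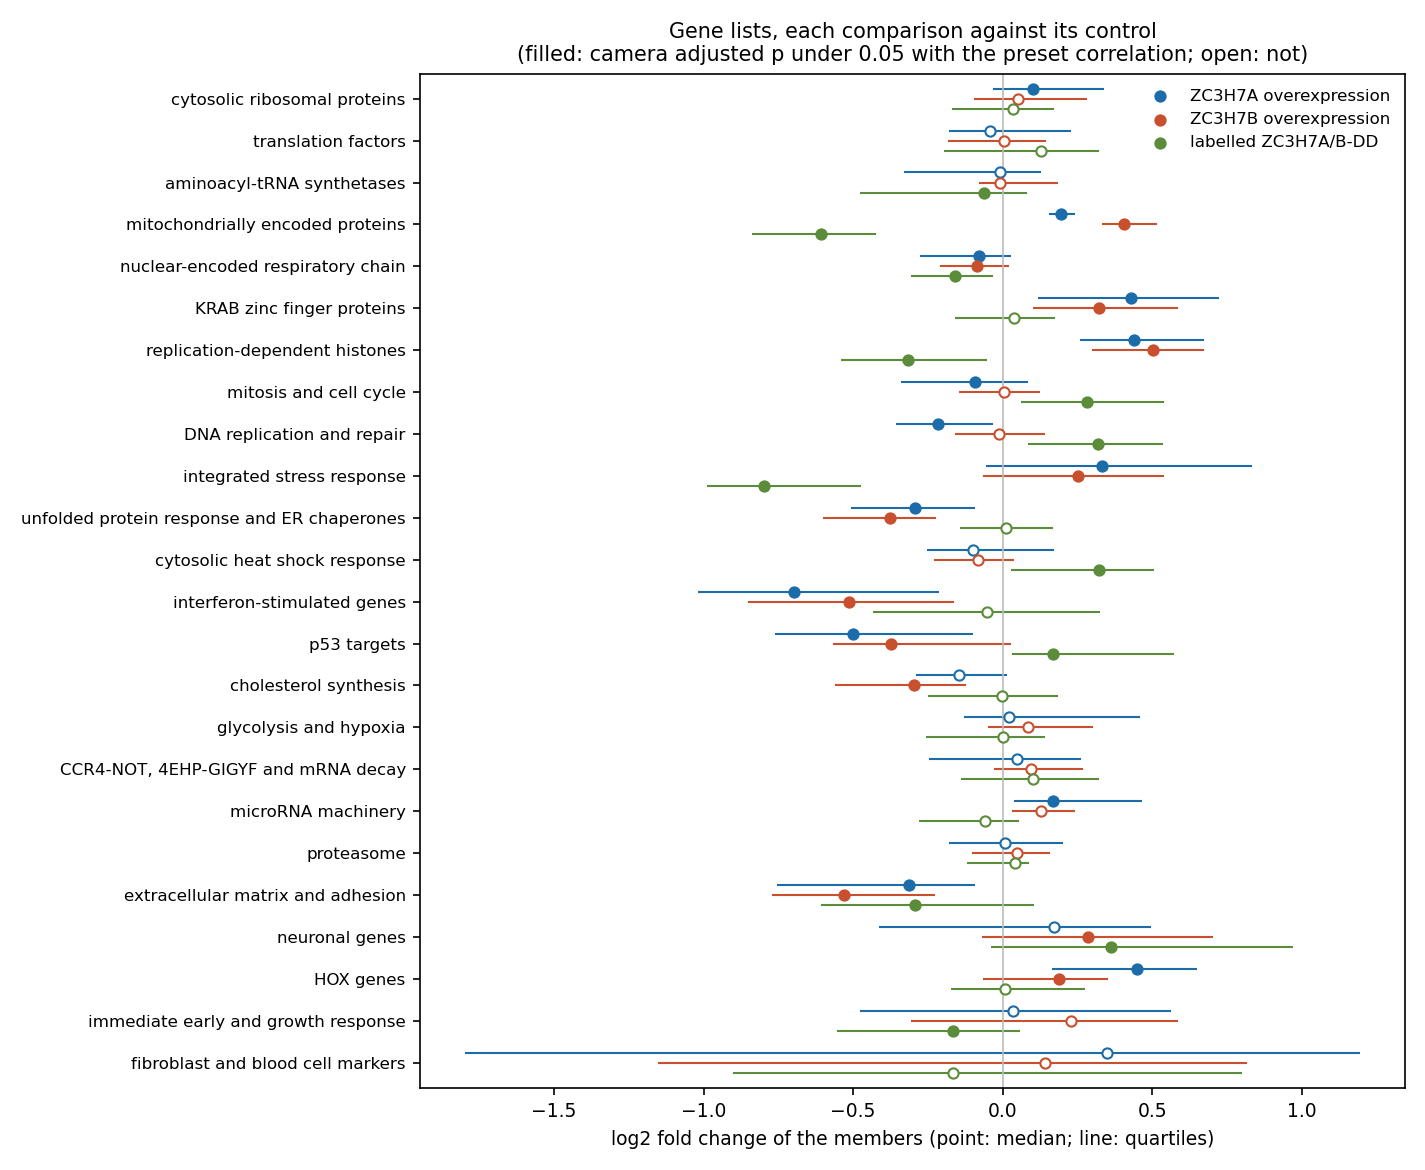
Median log2 change of each of the 24 gene lists in each comparison with a control, with filled points for lists past limma's camera test at the preset correlation and open points for the others. Histones rose in both overexpressions, with medians of 0.437 and 0.502, and were lower in the libraries labelled ZC3H7A/B-DD, with a median of -0.317.

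The 2 overexpressing lines were then compared with each other, which tests the difference between both responses and cancels the shared control. Of the 2 overexpressing lines, only that with ZC3H7A was high in IFI16, HDX, RPH3A and HIST1H2AL. HIST1H2AL was also high in the parental libraries, and HDX in those labelled ZC3H7A/B-DD. IFI16 stood at 1670.1 ± 103 against 10.5 ± 4.13 with ZC3H7B (log2 change 7.25). HDX was at 0 with ZC3H7B and at least 192-fold higher with ZC3H7A. MFAP2 and PABPC4L, with 1 read each in the ZC3H7A cells, stood at 298 ± 12.1 and 295 ± 22.1 with ZC3H7B, 119 to 26230 and 118 to 26060 times higher by the counting interval. The ephrin receptor EPHA6 stood at 3.66 ± 2.96 against 126 ± 6.42 (log2 change -4.96). RASAL1 and RAMP2, with 2 and 3 reads in the ZC3H7A cells, were 13.1 to 408 and 11.1 to 165 times higher with ZC3H7B, and the ratio for RPH3A, with 2 reads in the ZC3H7B cells, was 72.5 to 2179 in favour of ZC3H7A. In total 5705 of 15599 genes differed by limma's test, 2873 higher and 2832 lower with ZC3H7A, and 498 by at least 2-fold.

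DNA replication and repair genes had the smallest p among the lists, with 47 of 76 lower and 2 higher with ZC3H7A than with ZC3H7B (48 and 2 adjusted over the list alone, camera adjusted p = 1.15e-09, adjusted p = 0.702 with an estimated correlation). RPA2 stood at 3340 ± 139 against 8138 ± 867 (log2 change -1.28) and PRIM1 at -0.52. Mitosis genes were lower in 23 of 60 cases and higher in 6 (24 and 7 adjusted over the list alone, camera adjusted p = 0.00568, adjusted p = 0.751 with an estimated correlation), with SPC25 at -0.58 and SMC4 at -0.46. Cholesterol genes were higher with ZC3H7A in 16 of 24 cases and lower in 3 (17 and 3 adjusted over the list alone, camera adjusted p = 0.000116, adjusted p = 0.574 with an estimated correlation). SQLE stood at 10519 ± 205 against 7181 ± 301 (log2 change 0.55) and MSMO1 at 0.76. In the unfolded protein response 14 of 31 genes were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.00568, adjusted p = 0.751 with an estimated correlation). ERO1L was at 1.09 and DERL3 at -0.93. HOX genes were higher in 14 of 36 cases and lower in 3 (15 and 3 adjusted over the list alone, camera adjusted p = 0.00568, adjusted p = 0.751 with an estimated correlation), with HOXB4 at 1.13 and HOXA5 at -0.56. Mitochondrially encoded proteins were lower in 8 of 13 cases and the other 5 did not pass (10 were lower adjusted over the list alone, camera adjusted p = 0.00568, adjusted p = 0.751 with an estimated correlation), with MT-ND3 at -0.26.

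The remaining 5 lists passed that test but lost the call without single libraries. Aminoacyl-tRNA synthetases were lower with ZC3H7A in 9 of 20 cases and the other 11 did not pass, also adjusted over the list alone (camera adjusted p = 0.0148, adjusted p = 0.751 with an estimated correlation, 0.0534 without ZC3H7B replicate 2). FARSB stood at 5496 ± 172 against 9190 ± 778 (log2 change -0.74). Of 29 p53 targets 13 were lower and 5 higher (15 and 5 adjusted over the list alone, camera adjusted p = 0.0315, adjusted p = 0.574 with an estimated correlation, 0.0534 and 0.0574 without ZC3H7B replicates 2 and 3), with FDXR at -0.89. Ribosomal proteins were higher in 22 of 77 cases and lower in 5, also adjusted over the list alone (camera adjusted p = 0.0331, adjusted p = 0.779 with an estimated correlation). Without ZC3H7B replicates 2 and 3 in turn and ZC3H7A replicate 2 the adjusted p of camera was 0.0534, 0.14 and 0.207. RPL8 stood at 0.68 and RPL22 at -0.98. KRAB genes were higher in 64 of 245 cases and lower in 24 (63 and 24 adjusted over the list alone, camera adjusted p = 0.0315, adjusted p = 0.751 with an estimated correlation, 0.0594 without ZC3H7B replicate 2 and 0.0899 without ZC3H7A replicate 3). ZNF43 stood at 414 ± 16.6 with ZC3H7A against 4.37 ± 1.60 with ZC3H7B. The CCR4-NOT, 4EHP-GIGYF and mRNA decay list was lower in 17 of 49 cases and higher in 9 (18 and 9 adjusted over the list alone, camera adjusted p = 0.0442, adjusted p = 0.702 with an estimated correlation). EIF4E2, which encodes the cap-binding protein 4EHP, stood at 2128 ± 149 against 3824 ± 161 (log2 change -0.85) and XRN1 at 0.39. Its camera call was lost without ZC3H7B replicate 2 (0.059) and without ZC3H7A replicates 1 and 2 (0.0725 and 0.0533).

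The libraries labelled ZC3H7A/B-DD were compared with the parental line to ask what changes when both proteins are reduced, with the limit that the footprints of neither target were lower. The epithelial keratin KRT19 showed the strongest fall, from 2325 ± 188 normalized counts to 10.4 ± 4.61 (log2 change -7.77). MFAP2 fell from 978 ± 202 to 4.87 ± 2.84 (-7.49), CDH3 from 1149.7 ± 190.1 to 8.01 ± 0.325 (-6.98) and the retinoic acid binding protein CRABP2 from 3302 ± 640.2 to 37.7 ± 3.77 (-6.40). CHRDL1, a BMP antagonist, rose from 6.58 ± 0.792 to 238 ± 11.2 (log2 change 4.98). By limma's test 4182 of 17092 genes changed, 1873 higher and 2309 lower, with 844 at least 2-fold changed (408 higher, 436 lower). In 6967 genes (40.8%) the 2 groups' libraries did not overlap, against 10% by chance. The count of 4182 genes was 2517, 1959 and 5631 without parental replicates 1, 2 and 3, 2555 without replicate 3 of the libraries labelled ZC3H7A/B-DD and 9003 with precision weights in limma. Without the replicates 1 and 3 that had the higher ZC3H7A footprints, an alternative chosen after seeing the data, it was 968 (313 higher, 655 lower), 873 of them among the 4182.

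Other strong falls in the libraries labelled ZC3H7A/B-DD were of the retroviral envelope gene ERVMER34-1 (306 ± 43.6 to 2.35 ± 2.36), TSTD1 (305 ± 78.5 to 2.53 ± 2.01), the prostaglandin reductase PTGR1 (301 ± 6.64 to 3.67 ± 2.42), B3GALNT1 (310 ± 12.7 to 5.23 ± 0.920) and HIST1H2AL (2527 ± 116 to 51.2 ± 18.5). RBP7, with 1 read left, was 31.8 to 7107 times lower by the counting interval. MAGEC1 rose from 19.9 ± 4.75 to 458 ± 67.1, HDX from 11.7 ± 1.38 to 232 ± 32.6 and the interleukin receptor IL13RA2 from 4.72 ± 1.96 to 67.4 ± 9.88. RNA5-8SP2, a pseudogene of 5.8S ribosomal RNA, stood at 2254 ± 1509 against 169 ± 116 (log2 change 3.63), and reads from ribosomal RNA may be assigned to it. GPR78, MYO1G, AC105760.2 and JPH4 had log2 changes of 3.78, 3.47, 3.45 and 3.32. The first 3 of these lost their limma call without parental replicate 2 and without replicate 2 or 3 of the libraries labelled ZC3H7A/B-DD, where their smallest changes were 2.91, 2.65 and 2.60, all without replicate 3. GPR78 also lost it with the replicate block (3.78). JPH4 lost it without replicates 2 and 3 in turn (3.19 and 2.75).

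Of 37 integrated stress response genes, 27 fell and the other 10 did not pass in the libraries labelled ZC3H7A/B-DD (29 lower and 1 higher adjusted over the list alone, camera adjusted p = 7.11e-17, adjusted p = 0.237 with an estimated correlation). The glycoprotein hormone STC2 fell from 4000 ± 440 to 1142 ± 72.8 (log2 change -1.80) and the tRNA exporter XPOT from 5460 ± 224 to 2132 ± 134 (-1.36). Histones fell in 22 of 52 cases and rose in 1 (26 and 1 adjusted over the list alone, camera adjusted p = 3.67e-06, adjusted p = 0.529 with an estimated correlation), with HIST1H2BI at -2.61 and HIST1H2BG at 0.54. DNA replication and repair genes rose in 31 of 76 cases and fell in 2 (42 and 3 adjusted over the list alone, camera adjusted p = 1.55e-06, adjusted p = 0.746 with an estimated correlation). The helicase subunit MCM6 stood at 26349 ± 1555 against 14183 ± 3423 (log2 change 0.92) and GINS3 at -0.51. Mitosis genes rose in 18 of 60 cases and fell in 4 (25 and 4 adjusted over the list alone, camera adjusted p = 8.05e-05, adjusted p = 0.746 with an estimated correlation), with the kinetochore gene NDC80 at 0.96 and PTTG1 at -0.46. With replicates 1 and 3 left out together, which leaves 1 library, MCM6 (0.98), NDC80 (0.91), GINS3 (-0.435) and PTTG1 (-0.48) kept changes of similar size and lost their calls. They are among 45 calls of genes meeting the naming rule that were lost there, with HSPH1 (1.22), UCHL1 (-0.59), IFIT2 (1.81), GPR78 (4.39), AC105760.2 (3.70) and JPH4 (3.59) as the others named here for these libraries. Of 29 p53 targets 9 rose and 3 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.0056, adjusted p = 0.469 with an estimated correlation). CDKN1A rose from 1181 ± 73.1 to 3463 ± 604 (log2 change 1.54) and DDB2 by 0.98. Respiratory chain genes fell in 17 of 74 cases and the other 57 did not pass, also adjusted over the list alone (camera adjusted p = 0.00046, adjusted p = 0.746 with an estimated correlation), among them SDHB (from 9058 ± 491 to 3965 ± 186). Mitochondrially encoded proteins fell in 4 of 13 cases and the other 9 did not pass (5 fell adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.746 with an estimated correlation), with MT-CO1 at 25154 ± 4639 against 50029 ± 9402. The libraries overlapped, since these genes held 0.786%, 0.467% and 0.648% of reads in replicates 1 to 3 against 1.10%, 1.21% and 0.774% in the parental libraries.

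Neuronal genes rose in 11 of 24 cases and fell in 3 in the libraries labelled ZC3H7A/B-DD (12 and 3 adjusted over the list alone, camera adjusted p = 0.00189, adjusted p = 0.571 with an estimated correlation). The granins CHGA and CHGB rose by log2 changes of 2.06 and 2.14, while UCHL1 fell by 0.54. Immediate early and growth response genes fell in 10 of 31 cases and rose in 3 (12 and 4 adjusted over the list alone, camera adjusted p = 0.00505, adjusted p = 0.469 with an estimated correlation). MYC fell from 15320 ± 1124 to 6755 ± 464 (log2 change -1.18) and the growth factor signalling inhibitor SPRY4 by 2.44. Matrix and adhesion genes fell in 18 of 48 cases and rose in 7 (24 and 7 adjusted over the list alone, camera adjusted p = 0.0114, adjusted p = 0.746 with an estimated correlation, 0.0529 without replicates 1 and 3 together). SPARC rose from 306 ± 23.3 to 1729 ± 75.7 (log2 change 2.49) and AGRN fell by 1.45. Of 29 heat shock genes 9 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.0103, adjusted p = 0.746 with an estimated correlation). HSPH1 stood at 19615 ± 2402 against 8260 ± 2385 (log2 change 1.28) and HSPB1 at -1.18. This list lost its call without replicate 1 (adjusted p of limma's camera = 0.0594) and without replicates 1 and 3 together (0.0881). Aminoacyl-tRNA synthetases fell in 8 of 20 cases and rose in 1 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0442, adjusted p = 0.746 with an estimated correlation). MARS fell from 16396 ± 657 to 8690 ± 277 (log2 change -0.92) and YARS by 0.74. Their call was lost without parental replicate 3 (0.767), without replicate 2 (0.0721), replicate 3 (0.0859) or replicates 1 and 3 (0.0661) of the libraries labelled ZC3H7A/B-DD, and with the replicate block (0.0703).

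**Figure D3:**
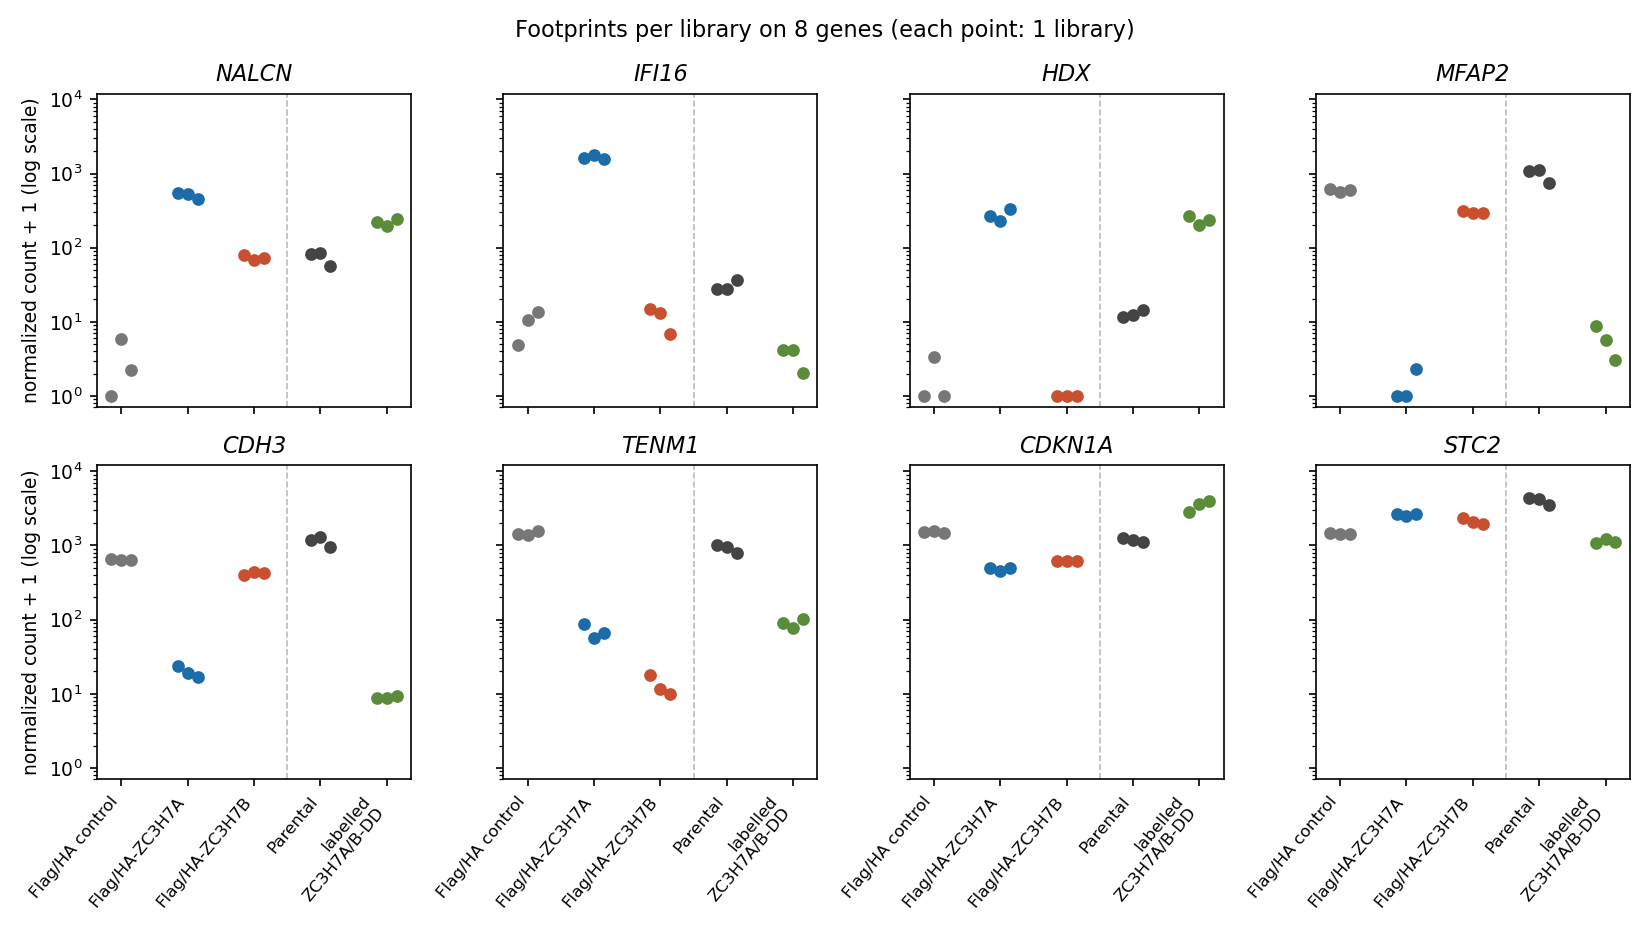
Normalized counts plus 1 (log axis) of 8 genes in all 15 libraries, with 1 point per library. MFAP2 and CDH3 were lower both with ZC3H7A overexpression and in the libraries labelled ZC3H7A/B-DD.

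The title of the series names codon dependence, so fold changes were compared with the share of codons that end in A or T in each coding sequence, called AT3. Genes rich in such codons fell with both overexpressed proteins. In the quintile of genes with the highest AT3 (58.6% to 78.7%, 2671 genes) 1348 genes fell and 506 rose with ZC3H7A, a median log2 change of -0.148 (camera adjusted p = 6.31e-08, adjusted p = 0.135 with an estimated correlation). In the quintile with the lowest AT3 (up to 24.4%) 1153 rose and 445 fell, with a median of 0.216 (camera adjusted p = 2.09e-05, adjusted p = 0.123 with an estimated correlation). With ZC3H7B 1323 fell and 475 rose in the highest quintile, at -0.152 (camera adjusted p = 6.3e-11, adjusted p = 0.0833 with an estimated correlation). In the lowest quintile 1096 rose and 361 fell, at 0.199 (camera adjusted p = 1.36e-05, adjusted p = 0.0833 with an estimated correlation). FARSA and FARSB, the paired subunits of phenylalanyl-tRNA synthetase, have AT3 of 20.3% and 62.4%. FARSA rose from 3227 ± 189 to 5223 ± 429 with ZC3H7A (log2 change 0.69) and FARSB fell from 10802 ± 276 to 5496 ± 172 (-0.97). Both changes were larger than the medians of their quintiles. List members were named for a small p, so this is no separate support for a link with AT3. FARSB also stood higher with ZC3H7B than with ZC3H7A, so AT3 alone does not give the size of its fall. ZC3H7A itself has AT3 of 64.2% and ZC3H7B 19.1%. Across 13354 genes, which are not independent replicates, Spearman's rho of AT3 with the log2 change was -0.268 with ZC3H7A and -0.295 with ZC3H7B. For the GC content of the whole coding sequence rho was larger in size, 0.2955 and 0.3174. At fixed GC content of the first and second codon positions, the partial rank correlation of AT3 was -0.124 and -0.151. With coding length and expression also fixed it was -0.0957 and -0.1185, so AT3 is not separated from base composition as a whole.

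Codon by codon, all 30 sense codons that end in A or T had negative correlations with the log2 change in both overexpressions, and 28 of the 31 that end in G or C had positive ones. The exceptions were TTG (-0.217 and -0.220), ATG (-0.124 and -0.123) and TGG (-0.0599 and -0.0754). The lowest correlation was that of ATT, an isoleucine codon, at -0.262 and -0.298, and the highest that of the proline codon CCC at 0.259 and 0.272. Each codon was correlated on its own, so these counts do not separate the third position from base composition. Per library, the slope on AT3 was -0.0778 ± 0.0149 per 10 points with ZC3H7A and -0.0833 ± 0.0132 with ZC3H7B, against a range of 0.0056 among the 3 controls. Each exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The 2 overexpressing lines were not told apart by AT3. Their highest and lowest quintiles differed by medians of 0.0095 and 0.0128 (camera adjusted p = 0.438 and 0.879), and the exact permutation test of their slopes gave p = 0.5.

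In the libraries labelled ZC3H7A/B-DD, in which target footprints were not lower, 505 genes of the highest AT3 quintile rose and 271 fell, with a median log2 change of 0.0954 (camera adjusted p = 0.00738, adjusted p = 0.766 with an estimated correlation). In the lowest quintile 275 rose and 474 fell, with a median of -0.0341 (adjusted p of limma's camera = 0.13). Single libraries decide this result. The slopes were 0.0798, -0.0231 and 0.0059 in replicates 1 to 3, against -0.0081, -0.0146 and 0.0227 in the parental libraries (exact two-sided permutation p = 0.7). The shift of the highest quintile from the median of all genes was 0.0152 without replicate 1, and it was -0.0177 without replicates 1 and 3 together. Across 13528 genes rho was 0.101, with -0.002 without replicate 1 and 0.185 without replicate 2.

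**Figure D4:**
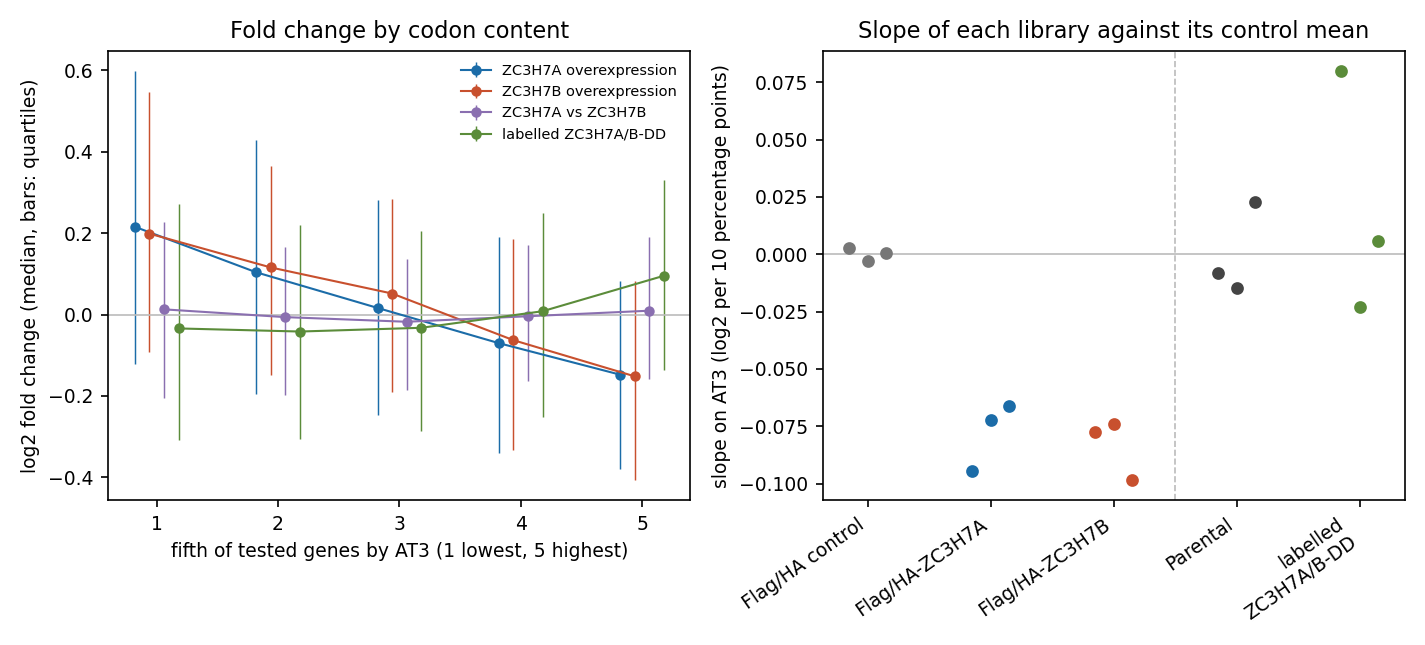
Median log2 change in quintiles of genes ordered by AT3, from low to high, and the AT3 slope of each library (log2 per 10 points of AT3). All 6 overexpressing libraries have slopes below the 3 controls, while the libraries labelled ZC3H7A/B-DD overlap the parental ones.

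The overexpression responses were finally set against each other and against the libraries labelled ZC3H7A/B-DD. With ZC3H7A and ZC3H7B 6505 genes were called in both, against 4870.2 for independent lists. Of these 3252 rose in both (1318 for independent lists), 2877 fell in both (1120.0), and 376 (5.8%) took opposite directions. The log2 changes had a Pearson correlation of 0.657 and a covariance of 0.275 across genes. Unchanged groups simulated against the same controls gave 0.498 and 0.0245, and 0.01 genes called in both on average over 100 simulations. Part of the excess may come from the shared controls, which are too few to split. The simulation held only independent noise of single libraries. It does not cover a control line that differs from both overexpressing lines, which would also give shared calls in the same direction. Among the 16 genes changed at least 8-fold in both, all took the same direction. NALCN, ZNF677, ZNF320, MUC16 and ULK2 rose, and SLC6A11, TMEM171, TENM1 and DLGAP1 fell.

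Genes called both with ZC3H7A and in the libraries labelled ZC3H7A/B-DD numbered 2650 of 14220 tested in both, against 2376.7 for independent lists. Of these, 1311 (49.5%) took opposite directions, with 509 up in both, 830.0 down in both, 684 up then down and 627 down then up. The odds ratio of the directions was 0.985 (95% interval 0.841 to 1.15, Fisher's exact p = 0.875), where 1 means no association. It was 1.61 without replicate 1 of the libraries labelled ZC3H7A/B-DD (Fisher's exact p = 2.84e-07), 1.36 without parental replicate 2 (Fisher's exact p = 0.00825) and 0.774 without replicate 2 (Fisher's exact p = 0.00554). For ZC3H7B 2421 genes were called in both, 1321 (54.6%) in opposite directions, with an odds ratio of 0.676 (95% interval 0.572 to 0.798, Fisher's exact p = 2.59e-06). That association was lost without parental replicate 3 (0.99, Fisher's exact p = 0.916) and without replicate 1 of the libraries labelled ZC3H7A/B-DD (0.994, Fisher's exact p = 0.961). Genes are not independent replicates, so the intervals and p-values of Fisher's test do not measure the spread between libraries. Leaving out 1 library moved the odds ratio for ZC3H7A to either side of 1. An exchange of the labels of both whole groups stays open. It would make the shares in opposite directions, 49.5% and 54.6%, those in the same direction, and would invert each odds ratio. CDKN1A fell in both overexpressions and rose in the libraries labelled ZC3H7A/B-DD, whose target footprints were not lower. STC2, XPOT and MYC were called lower there, and MYC was higher with ZC3H7A (log2 change 0.96). Other genes moved alike, since MFAP2, CDH3 and TENM1 fell and HDX rose both with ZC3H7A and in these libraries. Among genes changed at least 2-fold in both, 122 took the same direction and 66 the opposite with ZC3H7A, against 73 and 71 with ZC3H7B.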

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

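Of the tests given here, only the one for swapped libraries was chosen after its result was seen. The results listed first stand out because the responses to ZC3H7A and ZC3H7B differed by a direct test, with 5705 genes past limma's threshold. By log2 change, ZC3H7A minus ZC3H7B, the largest given here were HDX (8.10), HIST1H2AL (7.86), IFI16 (7.25) and RPH3A (7.14) on the higher side. On the lower side were MFAP2 (-7.82), PABPC4L (-7.81), EPHA6 (-4.96), RASAL1 (-4.845) and RAMP2 (-4.48). As the naming rule requires, all 3 libraries of one line lay above all 3 of the other for each of these genes. Where the lower line held only a few reads, the size of the log2 change depends on the value of 1 added before the logarithm. Lists that differed by limma's camera at the preset correlation had the median log2 changes below, ZC3H7A minus ZC3H7B, and all lost that call with an estimated correlation (adjusted p of limma's camera from 0.574 to 0.779). Cholesterol synthesis stood at 0.27, HOX genes at 0.203, the unfolded protein response at 0.087, ribosomal proteins at 0.075 and KRAB zinc fingers at 0.05. Mitochondrially encoded proteins stood at -0.237, p53 targets at -0.176, DNA replication and repair at -0.173, mitosis at -0.092, aminoacyl-tRNA synthetases at -0.07 and mRNA decay at -0.06. Each construct was measured in its own line, so differences between lines stay open for all of them.

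The first pattern is the fall of genes rich in codons ending in A or T in both overexpressions. At fixed AT3, the log2 change still followed the GC content of the first and second codon positions, with partial rank correlations of 0.130 for ZC3H7A and 0.123 for ZC3H7B, which is what a GC bias between libraries could give, so such a bias stays open. Expression level and coding length are argued against as the whole cause, because the partial correlations with AT3 given both were -0.221 and -0.242. The spread between single libraries is argued against too, since every overexpressing library lay at least 0.0633 below the lowest control slope, against a control range of 0.0056. In the libraries labelled ZC3H7A/B-DD, in which target footprints were not lower, the slopes overlapped those of the parental libraries (gap -0.0458) and the partial correlation was -0.0019 with -0.128 to 0.0847 over library pairs, so single libraries could account for that rise and a GC bias cannot be told apart, while a response to ZC3H7A and ZC3H7B dose stays open as untested.

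The second pattern is that ZC3H7A footprints stood above every parental library in replicates 1 and 3 of the libraries labelled ZC3H7A/B-DD. Reads mixed in from ZC3H7A-overexpressing libraries are argued against, since 36 marker genes of those libraries gave median shares of 0% in replicate 1 and -0.027% in replicate 3, where 13.4% and 8.05% would be needed. A swap of single libraries between the parental and the labelled group is argued against as well, because 6 of 6 libraries correlated more with each library of their own group than with any of the other. An exchange of the labels of both whole groups leaves these correlations unchanged, so it was not tested and stays open. So do samples of a similar line from outside these groups and a knockout allele whose transcript is still translated in part, neither of which these values test.

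The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, the real one included, which is too few for a share under 0.05. In each comparison 1 of the 10, the real split, called as many genes by limma. It called 8964 with ZC3H7A, 8475 with ZC3H7B, 5705 between them and 4182 in the libraries labelled ZC3H7A/B-DD, where the highest of the other splits was 0 in all 4 comparisons. Every other split mixes both groups, so a difference between the groups enters the spread and lowers the calls. Those splits therefore decide nothing.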

How the results depend on the processing

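The alternative without replicates 1 and 3 of the libraries labelled ZC3H7A/B-DD was chosen after seeing the data, and the others beforehand. Genes called in the ZC3H7A, ZC3H7B and ZC3H7A against ZC3H7B comparisons stayed within 1.5 times of 8964, 8475 and 5705 under every alternative except a 2-fold limit, which by construction left 1352, 1193 and 498, and 844 in the libraries labelled ZC3H7A/B-DD. Without single libraries these 3 counts ran from 8131 to 8587, 7581 to 8009 and 5009 to 5520. The balance of directions depended on the scaling. With TMM factors 4230 genes were higher and 4776 lower with ZC3H7A, and 4098 and 4370 with ZC3H7B, so more fell than rose. In the libraries labelled ZC3H7A/B-DD 1453 were higher and 2692 lower with TMM factors. For the libraries labelled ZC3H7A/B-DD the count of 4182 was 9003 with precision weights (4426 higher, 4577 lower), from 1959 without parental replicate 2 to 5631 without parental replicate 3, and 968 without replicates 1 and 3, which leaves 1 library assumed to vary like the others. The cause of the first was not tested. Deviations of same-numbered libraries correlated at -0.107 to 0.186 in the Flag/HA set, where other pairs reached 0.151. In the other set they correlated at -0.253 to -0.013, where other pairs reached 0.27. The best partner had the same number for 5 of 9 Flag/HA libraries and for 0 of 6 in the other set. Weak pairing by number is therefore not settled in the Flag/HA set and was not seen in the other. With the replicate number as a block limma called 9169, 8714, 6026 and 2992 genes. Gene lists called numbered 14, 12, 11 and 12 in the 4 comparisons. With an estimated correlation limma's camera called 0 in each, against 2, 5, 2 and 2 lists at an unadjusted p under 0.05. Without single libraries, lists called between the overexpressing lines ran from 6 (without ZC3H7B replicate 2) to 11. No list called at the preset correlation changed the sign of its median with TMM or quantile scaling.

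Against an estimated correlation the AT3 quintiles lost their call at shifts from the median of all genes of -0.170 and 0.193 with ZC3H7A, -0.188 and 0.163 with ZC3H7B and 0.0714 in the highest quintile of the libraries labelled ZC3H7A/B-DD. The shift of the lowest quintile between the overexpressing lines ran from -0.0002 to 0.0438 without single libraries. In the libraries labelled ZC3H7A/B-DD the highest quintile ran from 0.0152 (without replicate 1) to 0.122 (without replicate 2) and the lowest from -0.105 (without replicate 2) to -0.0001 (without replicate 1). Without replicates 1 and 3 these shifts were -0.0177 and 0.0294, the rank correlation with AT3 -0.0574, and the log2 changes of ZC3H7A and ZC3H7B -0.0771 and -0.0402. The turn of ZC3H7A follows from leaving out libraries chosen by their ZC3H7A level, and that of ZC3H7B was not tested. The log2 odds ratio of directions between ZC3H7A overexpression and the libraries labelled ZC3H7A/B-DD was -0.0217. It was 0.124 with the replicate block, 1.40 without replicates 1 and 3, and -0.369 (without replicate 2) to 0.688 (without replicate 1) without single libraries. For ZC3H7B it was -0.565, with 0.639 without replicates 1 and 3 and -1.04 (without replicate 2) to -0.0082 (without replicate 1). The cause of these turns was not tested, apart from fewer libraries. Of the calls of named genes 31 were lost without at least 1 of the single libraries, in 86 combinations of call and library, and none of these genes changed direction under the alternatives chosen beforehand. Depth limits genes with 0 to 3 reads in a group to bounds or counting intervals.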

Other observations

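Of the tests given here, those of the KRAB genes and of the genes switched nearly on or off with ZC3H7A were chosen only after the result was seen, and the same count for ZC3H7B was set beforehand. Several lists that did not pass limma's camera held members that moved apart. Among 43 translation factors 14 rose and 15 fell with ZC3H7A, also adjusted over the list alone, but 17 rose and 11 fell with quantile scaling. Their median log2 change was -0.041 (0.064 with quantile scaling), with a mean of 0.022 and a direction of down in limma's camera (adjusted p = 0.959). EEF1D, an exchange factor of elongation, rose from 2009 ± 49.5 normalized counts to 3504 ± 104 (log2 change 0.80), and the cap-complex scaffold EIF4G3 fell from 15338 ± 254 to 8402 ± 421 (-0.87). Aminoacyl-tRNA synthetases split 6 up and 7 down of 20, also adjusted over the list alone (camera adjusted p = 0.597). With quantile scaling they split 11 up and 6 down, and their median of -0.01 turned to 0.108. Of 27 heat shock genes 8 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.597). The chaperone HSPA1B, whose near-identical copy HSPA1A can share its reads, rose by a log2 change of 0.86 and DNAJB1 by 0.85, while the chaperonin subunits CCT8 and CCT5 fell (-0.63 and -0.56). Proteasome genes split 14 up and 12 down of 32 (15 and 12 adjusted over the list alone, camera adjusted p = 0.89), and their median of 0.008 turned to -0.022 with TMM scaling. They split 12 up and 13 down with TMM and 16 up and 9 down with quantile scaling. PSMC4 rose from 14190 ± 392 to 24936 ± 683 and PSMD1 fell from 22209 ± 795 to 14254 ± 467. In glycolysis and hypoxia 13 of 33 genes rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.17), with a median of 0.022 that turned to -0.008 with TMM scaling and with NDRG1 at 1.04, PFKFB3 at 1.10 and ENO1 at -0.53. Immediate early genes split 12 up and 11 down of 31 (12 and 12 adjusted over the list alone, camera adjusted p = 0.722) with a median of 0.033 that turned to -0.049 with quantile scaling, where MYC rose from 2780 ± 128 to 5419 ± 422 and JUN fell from 8849 ± 138 to 4707 ± 416. The mRNA decay list split 21 up and 13 down of 49, also adjusted over the list alone (camera adjusted p = 0.793), with CNOT7 at 0.47 and GIGYF2 at -0.56. Of 24 cholesterol genes 3 rose and 12 fell (camera adjusted p = 0.0683), and of 20 neuronal genes 9 rose and 6 fell (0.564).

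With ZC3H7B the mRNA decay list stood at the threshold, with 22 of 49 genes up and 7 down (camera adjusted p = 0.05, and 0.0396 without ZC3H7B replicate 3). LSM14B rose from 1588 ± 11.9 to 2393 ± 28.1 (log2 change 0.59) and the exonuclease XRN1 fell from 5680 ± 71.4 to 3369 ± 45.4 (-0.75). Glycolysis and hypoxia genes rose in 13 of 33 cases (camera adjusted p = 0.0942), and passed without control replicate 1 (0.0474) or ZC3H7B replicate 3 (0.0172). Ribosomal proteins split 30 up and 14 down of 77 (camera adjusted p = 0.269), with RPL22 at 2022 ± 151 against 999 ± 125. They split 24 up and 20 down with TMM scaling and 37 up and 10 down with quantile scaling. Mitosis and DNA replication lists had medians of 0.005 and -0.011 (camera adjusted p = 0.684 and 0.756), which turned to -0.028 with TMM and 0.096 with quantile scaling. Translation factors split 11 up and 16 down, but 17 up and 12 down with quantile scaling (camera adjusted p = 0.845, median 0.003, -0.029 with TMM and 0.066 with quantile scaling). Synthetases split 6 up and 4 down, but 5 up and 6 down with TMM scaling (0.623, median -0.009 and 0.09 with quantile scaling) and heat shock genes 6 up and 12 down (0.269). Proteasome genes split 12 up and 8 down (0.645), but 9 up and 11 down with TMM and 19 up and 5 down with quantile scaling. Immediate early genes split 15 up and 10 down (0.269) and the microRNA machinery 7 up and 2 down of 14 (camera adjusted p = 0.114). Between the 2 overexpressing lines 13 lists did not pass limma's camera, with adjusted p from 0.122 for interferon-stimulated genes (5 higher and 11 lower with ZC3H7A) to 0.886 for translation factors (8 and 8). Histones there had 4 genes higher and 11 lower, with a median of -0.066 but a mean of 0.339 (camera adjusted p = 0.42). In the libraries labelled ZC3H7A/B-DD, in which target footprints were not lower, KRAB genes split 19 up and 26 down of 237 (11 and 26 adjusted over the list alone, camera adjusted p = 0.931), with a median of 0.039, -0.003 with TMM scaling, and a mean of -0.128. Ribosomal proteins split 7 up and 8 down of 77, also adjusted over the list alone, with a median of 0.035, -0.008 with TMM scaling, and a mean of -0.025 (camera adjusted p = 0.931). Translation factors passed there only without parental replicate 3 (camera adjusted p = 0.0224). The other lists that did not pass there ran from an adjusted p of limma's camera of 0.288 for the microRNA machinery (1 up, 4 down) to 0.931 for the unfolded protein response, cholesterol synthesis, proteasome and HOX genes, with 0.486 for glycolysis and hypoxia and for mRNA decay. Interferon-stimulated genes split 7 up and 9 down of 36 (7 and 11 adjusted over the list alone, camera adjusted p = 0.486), with OAS3 at 10.6 ± 5.89 against 229 ± 8.79 and IFIT2 at 31.5 ± 3.82 against 9.36 ± 2.41. The microRNA regulator LIN28B changed by -1.04 there. Markers of fibroblasts and blood cells, of which 8 were tested, split 3 up and 3 down in each overexpression (camera adjusted p = 0.865 and 0.604) and 2 up and 3 down in the libraries labelled ZC3H7A/B-DD (0.931). The smooth muscle actin ACTA2 fell from 1601 ± 86.6 to 293 ± 35.7 with ZC3H7A and to 538 ± 12.9 with ZC3H7B.

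The third pattern is that KRAB zinc finger genes rose in both overexpressions although their coding sequences are rich in AT3, with a median of 61.5% against 41.0% over all genes. A hypothesis was that this class follows a rule beyond codon content. The median residual of 244 KRAB genes from the trend on AT3 and expression was 0.483 for ZC3H7A (quartiles 0.174 and 0.775) and 0.406 for ZC3H7B (0.163 and 0.661), and 0.015 in the libraries labelled ZC3H7A/B-DD, with target footprints not lower. A rise against a falling trend fixes the sign of the first 2 values, so they restate the pattern and do not test the hypothesis. A class rule, reads shared between near-identical zinc finger genes and differences between the lines therefore stay open.

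Of 13 genes changed at least 8-fold both with ZC3H7A and in the libraries labelled ZC3H7A/B-DD, 69.2% took the same direction (95% interval 38.6% to 90.9%), and of 6 such genes with ZC3H7B 66.7% did (22.3% to 95.7%). At 2-fold in both, 122 of 188 genes did with ZC3H7A (64.9%, 57.6% to 71.7%) and 73 of 144 with ZC3H7B (50.7%, 42.2% to 59.1%). If the labels of the parental and the labelled group were exchanged, which stays open, each of these would be the share in opposite directions. The 13 genes include CDH3, DECR1, HDX, HIST1H2AL, IFI16, LINC00958, MFAP2, OAS3, PABPC4L, RAMP2, TENM1 and ZNF826P. Differences between cell lines and a response to protein dose cannot be told apart for these genes, since each construct was measured in 1 line. The 95% intervals of the shares treat genes as independent, which they are not, and do not measure the spread between libraries.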
